A study of Mus musculus with 8 samples.

How the data were processed

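The samples were 8 RNA-seq libraries of Bruce 4 C57BL/6J mouse embryonic stem cells, 2 for each of 4 groups (gelatin or LN511 coating, Std or 2i medium). The design text calls them biological replicates. RNA was taken after 2 weeks in each condition, per the labels' protocols. The authors deposited FPKM values for genes, by symbol, and for transcripts, by RefSeq accession or by the number of an assembled transcript, one column per library. Per the submitters' processing notes, TopHat2 2.1.1, Cufflinks 2.1.1 and the genome build mm10 were used. Their roles and settings, the annotation, the strandedness of the libraries and any scaling between libraries are not given in the sources used here. All sample columns were used (0 were left out).

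The design fixed before the data were examined took gene values from the gene table. That table was examined before any test was run. Of the 52481 values that summed transcripts put at 1 FPKM or more, 24832 (47.3%) were listed at 0 in the gene table, and of 5 widely expressed genes looked up there, Pou5f1, Actb and Eef1a1 were above 0 in 2 of 8 libraries and Gapdh and Hprt in 7. Another 3544 expressed genes had no row there. Where both tables had a value above 0, 98.5% agreed within 0.1%. A zero there is therefore not a measurement, and the gene value used here is the sum of the FPKM of the RefSeq transcripts of the gene. This had been listed as an alternative, and the gene table now serves as the alternative instead. Of 32688 RefSeq transcripts, 31786 matched a symbol in the RefSeq gene table for GRCm38.p6, the assembly that mm10 names, and 902 did not, of which 108 had a mean of 1 FPKM or more. Coordinates are from that table. The other 21844 rows, of assembled transcripts, have numbers that name no common transcript across libraries and were left out, so reads given to them are missing from the sums. Dppa3 and Itgb1 had no transcript rows and were not tested.

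Genes with at least 1 FPKM in at least 2 libraries were kept (11244). A 0 in the transcript sums can also be a failed estimate. So 836 genes with 1 replicate at 0 and the other at 5 FPKM or more, and 130 genes with a whole group at 0 and another group's mean at 5 FPKM or more, were set aside, a rule chosen after looking at the structure of the files and before any test. Tet1 and Tet2 were among them. So were genes whose 0 may be a true low level. Egr1 of the ERK list was one, at 7.52 and 7.45 FPKM in gelatin Std, 0.13 and 0.12 in gelatin 2i and 0 and 0 in LN511 2i. The list tests and the largest changes leave such genes out. The filter and this rule left 10278 genes.

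The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend) on log2(FPKM + 1), with one mean per group and all 8 libraries in one fit, which leaves 4 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 6 contrasts: the medium on each coating, the coating in each medium, the mean of the coating contrasts and the interaction. Gene lists, 24 of them written from textbook knowledge before the data were examined, were tested with camera at a preset correlation of 0.01 where at least 5 members were tested (23 lists), adjusted over the lists within a contrast. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera takes p from the 4 residual degrees of freedom, so p rises even where the correlation is not above the preset one. The lists were naive pluripotency, core and shared pluripotency, formative and primed, Nodal signalling, ERK targets, Wnt and beta-catenin targets, DNA methylation machinery, germline genes, 2-cell-like genes, imprinted genes, integrins and laminin receptors, extracellular matrix, focal adhesion and actin, YAP and SRF targets, cholesterol and fatty acid synthesis (called lipid synthesis in the results), glycolysis, p53 targets, stress and immediate response, ribosomal proteins, and markers of primitive endoderm, trophoblast, mesendoderm, neuroectoderm and fibroblasts. Some genes are in more than 1 list, such as Krt18 among formative and primed genes and trophoblast markers. The Nodal signalling list also holds Fgf8, Bmp4, Id1, Id2 and Id3.

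The named genes were set by a rule written before the data were examined. For each comparison of 2 groups it took the 8 highest and 8 lowest fold changes among called genes with a mean of 5 FPKM or more in the higher group and no overlap of replicates, up to 3 members by adjusted p from each list that passed or had a called member, 1 member by fold change from other lists, and a fixed panel of pluripotency, DNA methylation, laminin receptor and signalling genes. For the interaction and for the mean of the coating contrasts it took 5 in each direction. Krt8 in the coating comparison in 2i and some genes of the closing section were named outside it, after their values were seen. The results of 2 genes that the rule names are not reported.

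Depth was read from low FPKM values. For single-transcript genes under 0.15 FPKM, 85.7% of 755 ratios between libraries were ratios of small whole numbers within 0.2%. This allowed for one factor per library, set at the most frequent ratio. Estimates of the depth from 401 single-transcript genes of 3000 bases or more had an interquartile range of 2300000 to 4600000 fragments. Each took the lowest value of its transcript as 1 fragment, and is too low where that value held more. The size of a step was thus ambiguous, so no value per library is given. The fit was tested on simulated data with the real means and spread for LN511 against gelatin in Std (10278 genes, 50 changed at each fold). It recovered 24% of genes changed 1.5-fold, 58% at 2-fold, 78% at 4-fold and 90% at 8-fold, and called 5 of 10078 unchanged genes. The changed genes were drawn only from those averaging about 5 FPKM or more, with the fold set on the log2(FPKM + 1) scale. Recovery of lower genes was therefore not tested. Alternatives were pseudocounts of 0.1 and 0.5, no filter or a filter of 5 FPKM, median-of-ratios and quantile scaling, the replicate number as a block, robust eBayes, only the libraries of the contrast, the deposited gene table, a log2 fold change of 1 or more, and leaving out each library. Keeping genes with a doubtful 0, and testing only genes above 0 in all 8 libraries, were added after seeing the data. Tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.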

Results

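RNA was sequenced from the male C57BL/6J mouse embryonic stem cell line Bruce 4 after 2 weeks of culture on dishes coated with laminin-511 (LN511) or with gelatin, in 1 of 2 media. One medium is called Std in the labels, which do not give its composition. The other is 2i, a medium that holds inhibitors of MEK and of GSK3 and keeps embryonic stem cells in a naive state. The 4 combinations of coating and medium had 2 biological replicates each, 8 libraries in all. Expression is given in FPKM (fragments scaled by transcript length and by library depth), here summed over the RefSeq transcripts of each gene. The files give no read counts. The steps between low FPKM values put the depths of the 8 libraries within 1.19-fold of one another. Estimates of the depth from single transcripts had an interquartile range of 2300000 to 4600000 fragments and may be too low. At those depths, 1 step on a transcript of 2000 bases is about 0.11 to 0.22 FPKM. By these estimates low values are coarse. Across genes, Pearson correlations of log2(FPKM + 1) were 0.959 to 0.964 between replicates and 0.907 to 0.955 between libraries of different groups. Below, levels are means ± SD of the 2 libraries of a group, fold changes are differences on the log2(FPKM + 1) scale with their standard error (SE), which understate the change of low genes, and adjusted p-values come from limma over 10278 genes. The deposited table of gene values, which the design had named as the source, lists at 0 47.3% of the values that the transcript sums put at 1 FPKM or more. Fits to that table gave very different counts of genes and turned the direction of several genes named below.

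The first comparison asked what 2i medium changed on gelatin. Nanog, a homeodomain factor of the naive pluripotency network (mm10 chromosome 6, 122707489 to 122714633), rose from 54.9 ± 2.59 to 451 ± 6.14 FPKM, a log2 fold change of 3.02 (SE 0.09, limma adjusted p = 2.57e-05). Tfcp2l1, another naive factor, rose from 5.34 ± 0.54 to 146 ± 0.71 FPKM, and Klf4 from 20.1 ± 1.09 to 94.1 ± 3.15 FPKM. The POU factor Pou3f1, of the formative and primed states, fell from 43.0 ± 2.96 to 0.70 ± 0.03 FPKM. Dusp6, a phosphatase gene induced by ERK signalling, fell from 47.4 ± 1.37 to 1.48 ± 0.08 FPKM (log2 -4.28, SE 0.22, limma adjusted p = 0.000129).

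Of 17 tested naive pluripotency genes, 13 rose and 1 fell in 2i on gelatin (14 and 2 adjusted over the list alone), with a median log2 fold change of 2.49. The list differed from other genes by camera (adjusted p = 2.25e-11) and also with an estimated correlation (adjusted p = 0.0353). Jam2, Tdh, Esrrb, Prdm14 and Zfp42 were among those that rose. The member that fell was Gbx2 (log2 -0.96, SE 0.25). The core factor Pou5f1 did not pass the test, at 982 ± 46.9 FPKM in Std and 1059 ± 34.3 FPKM in 2i, and Sox2 rose by a log2 fold change of 0.31 (SE 0.08). Among 11 core and shared pluripotency genes, 1 rose and 3 fell (1 and 6 adjusted over the list alone). Those that fell were Utf1 (log2 -2.08), Tdgf1 (log2 -0.85) and Lin28a (log2 -0.80). That list passed with the preset correlation (adjusted p = 0.0356) but not with an estimated one (adjusted p = 0.265 with an estimated correlation). Its call was also lost (camera adjusted p in brackets) for core and shared pluripotency genes without gelatin Std replicate 1 (0.122), gelatin 2i replicate 1 (0.0771), LN511 2i replicate 1 (0.0614) or LN511 2i replicate 2 (0.0616).

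Of 16 formative and primed genes, 11 fell and none rose on gelatin, the same numbers as adjusted over the list alone (camera adjusted p = 1.6e-06, adjusted p = 0.0556 with an estimated correlation). The de novo DNA methyltransferases Dnmt3a and Dnmt3b belong to this list. Dnmt3a (mm10 chromosome 12, 3801559 to 3914443) fell from 75.4 ± 0.38 to 4.54 ± 0.19 FPKM, and Dnmt3b from 191 ± 97.1 to 20.1 ± 7.80 FPKM, with a wide spread between the Std libraries. In Std medium, on either coating, the Dnmt3a sum lay in a single RefSeq transcript, the others being listed at 0. Their cofactor Dnmt3l fell from 519 ± 39.8 to 141 ± 16.4 FPKM, while Uhrf1, which guides the maintenance methyltransferase, rose from 134 ± 0.10 to 255 ± 10.1 FPKM. The maintenance enzyme itself, Dnmt1, was at 82.5 ± 1.65 FPKM in Std and 82.4 ± 2.98 FPKM in 2i (log2 -0.00, SE 0.20). The list of 13 DNA methylation genes had 3 members up and 3 down (also 3 and 3 adjusted over the list alone) and did not move as a list (camera adjusted p = 0.422).

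ERK pathway targets fell on gelatin in 7 of 14 cases, with none higher and the same 7 adjusted over the list alone (camera adjusted p = 0.000119, adjusted p = 0.0772 with an estimated correlation). Spry4, a feedback inhibitor, fell from 23.6 ± 1.58 to 3.87 ± 0.11 FPKM. Glycolysis genes fell in 8 of 20 cases and rose in 1 (10 and 3 adjusted over the list alone; camera adjusted p = 0.000248, adjusted p = 0.119 with an estimated correlation), with Pdk1 at log2 -2.19 and Pgk1, at 806 FPKM in Std and 404 FPKM in 2i, among those that fell. Of 20 imprinted genes, 8 fell and 2 rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.000986, adjusted p = 0.0898 with an estimated correlation), with Mest falling from 47.3 ± 0.33 to 9.98 ± 2.21 FPKM. Germline genes fell in 4 of 18 cases (6 adjusted over the list alone; camera adjusted p = 0.0019, adjusted p = 0.0903 with an estimated correlation), including Mael and Syce1. Among 16 p53 targets, 6 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0225, adjusted p = 0.152 with an estimated correlation); Ddit4 fell (log2 -2.20) while the cell cycle inhibitor Cdkn1a rose (log2 1.11). Of 5 tested mesendoderm markers, Eomes, Gsc and T rose (4 adjusted over the list alone; camera adjusted p = 0.0123, adjusted p = 0.197 with an estimated correlation). Their levels in 2i were low, 5.33 ± 0.66 FPKM for Eomes, and Gsc and T were listed at 0 in both gelatin Std libraries. With 1 library left out, the camera call was lost, at the adjusted p in brackets, for p53 targets without gelatin Std replicate 2 (0.0674).

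In all, 1583 of 10278 genes passed on gelatin, 843 higher and 740 lower in 2i. The largest rises by the naming rule also included Calcoco2, an autophagy receptor gene (4.69 ± 0.40 to 166 ± 7.16 FPKM), the homeobox gene Cdx1 (0.63 ± 0.52 to 45.4 ± 4.29 FPKM), the aquaporin Aqp3 and the creatine kinase Ckb. The largest falls also included the kinase Pim2 (164 ± 1.81 to 7.41 ± 0.64 FPKM), Enpp3, Hes6 and Gadd45g. Leaving out 1 library of the comparison lowered the count to 811 without gelatin Std replicate 1, 767 without gelatin Std replicate 2, 648 without gelatin 2i replicate 1 and 688 without gelatin 2i replicate 2. The fit to the deposited gene table called 273. Of 79 called genes that the naming rule takes for this comparison, 23 missed the threshold with some library left out (limma adjusted p in brackets). They include Tdrd1, H19, Lmna, Ajuba, Amn, Krt8, Gata2, Nes, Ncam1, Pdgfrb, Rplp0, Ilk, Ccn1, Itga5 and Fgf5 (0.0508 to 0.175 where missed). Lin28a missed it without gelatin Std replicate 1 (0.0752), gelatin Std replicate 2 (0.0944) or gelatin 2i replicate 1 (0.0685). Mael missed it without gelatin Std replicate 1 (0.0531) or gelatin Std replicate 2 (0.0513). Syce1 missed it without gelatin Std replicate 1 (0.0602) or gelatin 2i replicate 1 (0.0578). Gsc missed it without gelatin Std replicate 2 (0.0503), gelatin 2i replicate 1 (0.0548) or gelatin 2i replicate 2 (0.0532). T missed it without gelatin Std replicate 1 (0.0701), gelatin Std replicate 2 (0.0722), gelatin 2i replicate 1 (0.0905) or gelatin 2i replicate 2 (0.0544). Gbx2 missed it without gelatin Std replicate 1 (0.163), gelatin Std replicate 2 (0.136), LN511 Std replicate 1 (0.0802), LN511 Std replicate 2 (0.0805), gelatin 2i replicate 1 (0.115) or gelatin 2i replicate 2 (0.178). Sox2 missed it without gelatin Std replicate 1 (0.152), gelatin Std replicate 2 (0.0845), LN511 Std replicate 1 (0.0649), LN511 Std replicate 2 (0.0649), gelatin 2i replicate 1 (0.167) or gelatin 2i replicate 2 (0.0777). Gbx2 also missed it with a pseudocount of 0.1 (0.0578), with no filter (0.0637) and with doubtful zeros kept (0.0609). Sox2 missed it with quantile normalization (0.103), and Sox2 and Lin28a with only the 4 gelatin libraries (0.0792 and 0.0678).

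**Figure D1:**
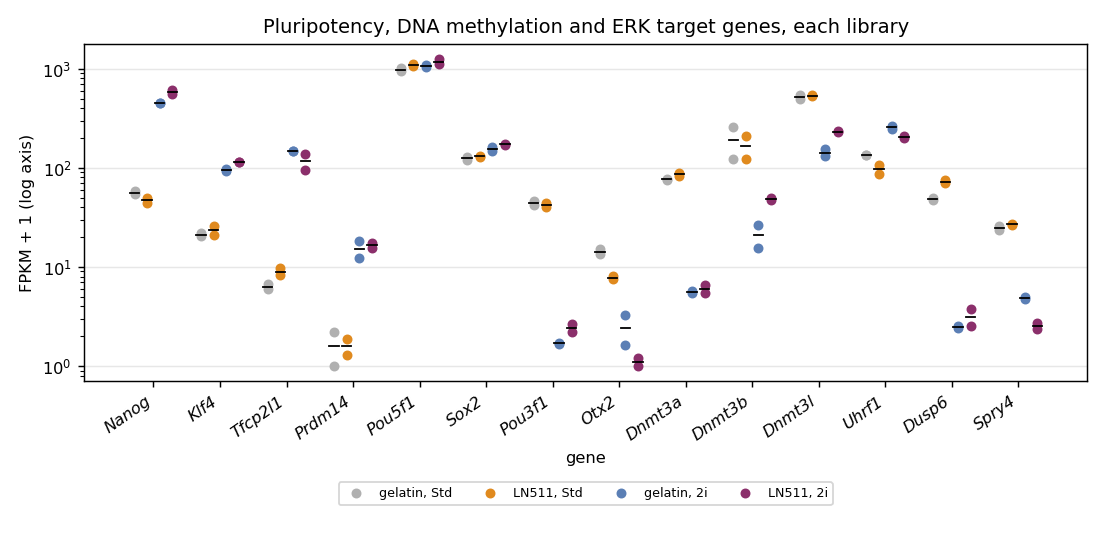
FPKM + 1 on a log axis for 14 genes in each of the 8 libraries, coloured by coating and medium, with a black line at the mean of the 2 libraries of a group. Nanog lies at 54.9 and 45.8 FPKM in the Std groups and 451 and 582 FPKM in the 2i groups (gelatin, then LN511), and Dnmt3a at 75.4 and 84.8 against 4.54 and 5 FPKM.

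The same comparison on LN511 gave 1905 genes, 882 higher and 1023 lower in 2i. Nanog rose from 45.8 ± 3.70 to 582 ± 45.3 FPKM (log2 3.64, SE 0.09, limma adjusted p = 1.45e-05), and Klf2, a naive factor, from 11 ± 2.04 to 122 ± 20.1 FPKM. Pou3f1 fell from 41.3 ± 2.34 to 1.40 ± 0.32 FPKM, Dusp6 from 71.5 ± 3.70 to 2.15 ± 0.89 FPKM and Dnmt3a from 84.8 ± 3.37 to 5 ± 0.82 FPKM. Krt8 and Krt18, the keratin pair of simple epithelia, fell by 2.70 (SE 0.16) and fell by 3.13 (SE 0.26) on the log2 scale.

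Naive pluripotency genes rose on LN511 in 12 of 17 cases and fell in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 1.83e-10, and adjusted p = 0.0415 with an estimated correlation). Esrrb did not pass here, at 50.1 ± 5.19 FPKM in Std and 89.8 ± 12.9 FPKM in 2i, and its interaction did not pass (limma adjusted p = 0.244). Formative and primed genes fell in 8 of 16 cases and rose in 1 (12 and 2 adjusted over the list alone, camera adjusted p = 0.0003, adjusted p = 0.0947 with an estimated correlation). That list also holds the keratin gene Krt18, whose fall is given above. ERK targets fell in 9 of 14 cases, 9 also adjusted over the list alone (camera adjusted p = 0.000394, adjusted p = 0.0947 with an estimated correlation), and Ccnd1, the cyclin D1 gene, was 1 of them (log2 -1.19). Wnt and beta-catenin targets rose in 5 of 11 cases and fell in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00505, adjusted p = 0.0947 with an estimated correlation). Cdx1 rose from 1.64 ± 0.58 to 36.4 ± 3.46 FPKM and Axin2, a feedback target of the pathway, from 1.67 ± 0.95 to 7.15 ± 2.14 FPKM. On gelatin, 3 members of that list rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.154).

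Focal adhesion and actin genes fell in 11 of 27 cases and rose in 2 in 2i on LN511 (13 and 2 adjusted over the list alone; camera adjusted p = 0.00505, adjusted p = 0.0947 with an estimated correlation), including Zyx and S100a6 (log2 -3.59). Glycolysis genes fell in 10 of 20 cases and rose in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.000394, adjusted p = 0.0947 with an estimated correlation). For p53 targets, 6 of 16 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.00505, adjusted p = 0.0947 with an estimated correlation), and for imprinted genes 10 of 20 fell and 2 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.00742, adjusted p = 0.0947 with an estimated correlation). Peg10, an imprinted gene, fell from 87.4 ± 24 to 2.99 ± 2.41 FPKM. Of 9 Nodal signalling genes, 4 fell, 4 also adjusted over the list alone (camera adjusted p = 0.0409, adjusted p = 0.238 with an estimated correlation). Its member Lefty1, a Nodal antagonist, fell by 4.65 (SE 0.35) on the log2 scale. As the list also holds Bmp4, Id1, Id2 and Id3, its result is not particular to Nodal. On gelatin that list had 3 members down and 1 up (3 and 2 adjusted over the list alone; camera adjusted p = 0.36). Trophoblast markers fell in 7 of 15 cases and rose in 1 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0414, adjusted p = 0.238 with an estimated correlation). Genes of the 2-cell-like state rose in 2 of 10 cases, Gm5662 and Zscan4c (5 adjusted over the list alone; camera adjusted p = 0.0148, adjusted p = 0.115 with an estimated correlation), both calls being lost when single libraries were left out. These belong to families of near-identical copies, so their values are uncertain. Ribosomal protein genes had 3 members up and 1 down of 26 (3 and 1 adjusted over the list alone; camera adjusted p = 0.0414, adjusted p = 0.49 with an estimated correlation), with a median log2 fold change of only 0.07. With a pseudocount of 0.1 the camera call was lost for Nodal signalling genes (adjusted p = 0.0672) and trophoblast markers (adjusted p = 0.0649). Camera calls lost on leaving out 1 library, with the adjusted p in brackets, were those of Nodal signalling genes without LN511 Std replicate 1 (0.0872) or LN511 2i replicate 2 (0.058), trophoblast markers without LN511 Std replicate 1 (0.103), gelatin 2i replicate 1 (0.059), gelatin 2i replicate 2 (0.0593) or LN511 2i replicate 1 (0.0858), and ribosomal protein genes without LN511 Std replicate 1 (0.147), gelatin 2i replicate 1 (0.059), gelatin 2i replicate 2 (0.0593) or LN511 2i replicate 2 (0.475).

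The medium comparisons on the 2 coatings share no libraries, but they share 1 estimate of each gene's spread, so their lists are not independent. They had 490 higher genes in common, where independent lists would share 72.3, and 477 lower genes, where independent lists would share 73.7. Another 22 genes passed on both coatings in opposite directions, 17 of them higher in 2i on gelatin and 5 lower. Leaving out a library gave 863 genes without LN511 Std replicate 1 (452 higher and 411 lower), 861 without LN511 Std replicate 2 (467 higher and 394 lower) and 1211 without LN511 2i replicate 2, against 1905. The fit to the deposited gene table called 336. Of 82 called genes that the naming rule takes for this comparison, 19 missed the threshold with some library left out (limma adjusted p in brackets). They include Mov10l1, Sdc1, Vgll3, Idi1, T, Thy1, Rps18, Rplp0, Sox2, Dnmt3b, Itga6, Tdrd1, Itgb5, F3, Nes and Rps23 (0.0513 to 0.17 where missed). Gm5662 missed it without gelatin Std replicate 1 (0.0572), gelatin Std replicate 2 (0.0573), LN511 Std replicate 1 (0.0676), LN511 Std replicate 2 (0.156), gelatin 2i replicate 1 (0.05), gelatin 2i replicate 2 (0.0502), LN511 2i replicate 1 (0.0534) or LN511 2i replicate 2 (0.139). Zscan4c missed it without gelatin Std replicate 1 (0.0563), gelatin Std replicate 2 (0.056), LN511 Std replicate 1 (0.0953), LN511 Std replicate 2 (0.158), gelatin 2i replicate 1 (0.0611), gelatin 2i replicate 2 (0.0611) or LN511 2i replicate 1 (0.131). Axin2 missed it without LN511 Std replicate 2 (0.131), LN511 2i replicate 1 (0.116) or LN511 2i replicate 2 (0.0555). With no filter Gm5662, Zscan4c and Axin2 missed it as well (0.0508 to 0.0652), and with only the 4 LN511 libraries too (0.0814 to 0.101). Gm5662 also missed it with a pseudocount of 0.1 (0.0605), and Zscan4c with doubtful zeros kept (0.0544).

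The coating comparison in Std medium asked what LN511 changed against gelatin. The keratin gene Krt8 (mm10 chromosome 15, 101996711 to 102004342) rose from 4.98 ± 0.30 to 90.4 ± 4.28 FPKM, a log2 fold change of 3.93 (SE 0.16, limma adjusted p = 0.000351). Its partner Krt18 rose from 10.5 ± 0.34 to 76.1 ± 0.86 FPKM, and Krt19 from 2.56 ± 0.61 to 20.2 ± 2.49 FPKM. Ccn1, a secreted matrix protein gene and YAP target (mm10 chromosome 3, 145646971 to 145649985), rose from 10.8 ± 0.66 to 78.1 ± 0.52 FPKM (log2 2.74, SE 0.11). Of 17 naive pluripotency genes 0 passed (1 higher adjusted over the list alone; camera adjusted p = 0.248), and of 11 core and shared ones Tdgf1 fell (log2 -0.47; 1 lower also adjusted over the list alone; camera adjusted p = 0.248). Nanog was at 54.9 ± 2.59 FPKM on gelatin and 45.8 ± 3.70 FPKM on LN511, and Pou5f1 at 982 ± 46.9 and 1093 ± 28.1 FPKM. Krt8 and Ccn1 passed with any 1 library left out. Krt18 and Krt19 missed the threshold when a library was left out, at limma adjusted p = 0.0595 and 0.0666 without gelatin Std replicate 1, 0.0521 and 0.0521 without gelatin Std replicate 2, 0.0746 and 0.0972 without LN511 Std replicate 1, and 0.0678 and 0.0719 without LN511 Std replicate 2.

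Of 27 focal adhesion and actin genes, 9 rose on LN511 in Std and none fell (19 and 0 adjusted over the list alone). This list differed from other genes with the preset correlation (camera adjusted p = 1.12e-13) and with an estimated one (adjusted p = 0.0211), with a median log2 fold change of 0.85. The calponin Cnn2 rose from 16.3 ± 2.29 to 61.9 ± 3.40 FPKM, the tropomyosin Tpm4 from 41.3 ± 3.58 to 88.9 ± 0.78 FPKM and the actinin Actn4 from 155 ± 11.6 to 274 ± 2.61 FPKM. YAP and SRF targets rose in 2 of 11 cases, Ccn1 and Ccn2 (5 adjusted over the list alone; camera adjusted p = 0.000975, adjusted p = 0.103 with an estimated correlation). Among 15 integrins and laminin receptors, Bcam and Itga1 rose (also 2 adjusted over the list alone; camera adjusted p = 0.00324, adjusted p = 0.103 with an estimated correlation). Bcam, which encodes a receptor for the laminin alpha 5 chain, rose from 46.8 ± 6.86 to 129 ± 1.21 FPKM. Itga6, which encodes the alpha chain of the integrin that binds laminin-511, was at 31.6 ± 1.87 FPKM on gelatin and 38.1 ± 0.10 FPKM on LN511 and did not pass.

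Lists of markers of other cell types gave mixed results in Std. Trophoblast markers rose in 4 of 15 cases, Krt8, Krt18, Krt19 and Hand1 (9 adjusted over the list alone, with 1 lower; camera adjusted p = 3.02e-06, adjusted p = 0.103 with an estimated correlation). Keratins are made by many epithelia. Hand1, a factor of trophoblast and mesoderm, was low, at 0.24 ± 0.34 FPKM on gelatin and 2.73 ± 0.55 FPKM on LN511. None of 7 neuroectoderm markers passed singly (2 adjusted over the list alone), though the list did (camera adjusted p = 0.024, adjusted p = 0.329 with an estimated correlation). For 6 fibroblast markers the test was not passed (camera adjusted p = 0.293), and none of these was called. Of 5 mesendoderm markers Hand1 alone was called (1 adjusted over the list alone; camera adjusted p = 0.163). Only 3 primitive endoderm markers could be tested, and none passed; Dab2 was at 1.05 ± 0.55 and 1.71 ± 0.31 FPKM. Leaving out 1 library ended the camera call (adjusted p in brackets) of neuroectoderm markers without gelatin Std replicate 2 (0.0788) or LN511 Std replicate 2 (0.15).

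ERK targets rose in 2 of 14 cases on LN511 in Std, the receptor Epha2 (60.4 ± 0.04 to 134 ± 2.28 FPKM) and Ccnd1 (3 adjusted over the list alone; camera adjusted p = 0.024, adjusted p = 0.159 with an estimated correlation). Lipid synthesis genes fell in 2 of 23 cases, the desaturases Scd1 and Scd2 (also 2 adjusted over the list alone; camera adjusted p = 0.00221, adjusted p = 0.103 with an estimated correlation). Of 18 germline genes, Hormad1 fell (2 adjusted over the list alone; camera adjusted p = 0.024, adjusted p = 0.159 with an estimated correlation). None of 26 ribosomal protein genes passed singly (0 adjusted over the list alone; camera adjusted p = 0.00975, adjusted p = 0.417 with an estimated correlation), and the median log2 fold change was -0.07. Extracellular matrix genes had 2 members up and 1 down of 19 (5 and 3 adjusted over the list alone) and did not move as a list (camera adjusted p = 0.212). Sparc and Col4a1 were those that rose. Stress genes had no called member of 12 (2 up and 1 down adjusted over the list alone; camera adjusted p = 0.268). Calls that ended on leaving out 1 library, by camera adjusted p in brackets, were those of ERK targets without gelatin Std replicate 2 (0.0788) or LN511 Std replicate 2 (0.15), germline genes without gelatin Std replicate 1 (0.119) or LN511 Std replicate 1 (0.109), and ribosomal protein genes without LN511 Std replicate 1 (0.0794).

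The largest rises on LN511 in Std by the naming rule also included the annexin Anxa3 (0.95 ± 0.76 to 19.3 ± 2.13 FPKM), the transglutaminase Tgm1 (4.94 ± 1.55 to 36.7 ± 9.42 FPKM), Thbs1, Tinagl1 and the RNase P RNA Rpph1. The largest falls by that rule were Xlr3b (9.64 ± 0.05 to 0.38 ± 0.04 FPKM), Zfp229, Mtmr3, Xlr3a, Zfp985, Rpl39l, Igf2bp2 and Hormad1. Xlr3a and Xlr3b are close copies on chromosome X, so how reads were divided between them is uncertain. In all, 216 genes passed, 158 higher and 58 lower on LN511. The count fell to 39 without gelatin Std replicate 1, 41 without gelatin Std replicate 2, 9 without LN511 Std replicate 1 (5 higher and 4 lower), 18 without LN511 Std replicate 2 (9 higher and 9 lower), 75 without gelatin 2i replicate 1 and 74 without gelatin 2i replicate 2. With only the 4 Std libraries in the fit, 6 genes passed.

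Of 41 called genes that the naming rule takes for the coating in Std, 39 missed the threshold with some library left out, all but Krt8 and Ccn1. Of those described above as higher or lower on LN511, only Krt8, Ccn1 and Zfp229 passed without LN511 Std replicate 1 (the others at limma adjusted p = 0.0703 to 0.183). Only Krt8, Ccn1, Xlr3a, Rpl39l and Bcam passed without LN511 Std replicate 2 (the others at 0.0513 to 0.211). Without gelatin Std replicate 1, Krt8, Anxa3, Ccn1, Tgm1, Thbs1, Xlr3b, Bcam, Cnn2 and Tpm4 passed and the others did not (0.0533 to 0.139). Without gelatin Std replicate 2, Krt8, Anxa3, Ccn1, Xlr3b, Ccnd1, Bcam, Sparc, Cnn2, Tpm4 and Actn4 passed and the others did not (0.0509 to 0.168). Rpph1, Tinagl1, Zfp229, Mtmr3, Zfp985, Rpl39l, Hormad1, Tdgf1, Ccnd1, Itga1, Col4a1, Ccn2, Scd1 and Hand1 missed the threshold without gelatin 2i replicate 1 (0.0516 to 0.0921) or gelatin 2i replicate 2 (0.052 to 0.0929). Zfp229, Mtmr3, Itga1, Col4a1, Ccn2, Scd1 and Hand1 missed it without LN511 2i replicate 1 (0.0523 to 0.0817) or LN511 2i replicate 2 (0.0523 to 0.0817). With only the 4 Std libraries, Krt8, Krt18 and Ccn1 passed, and the others described above had limma adjusted p = 0.0646 to 0.172. Under at least 1 other pseudocount, filter, scaling or moderation, Tinagl1, Thbs1, Zfp229, Mtmr3, Itga1, Col4a1, Scd1 and Hand1 missed the threshold (0.0512 to 0.196).

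**Figure D2:**
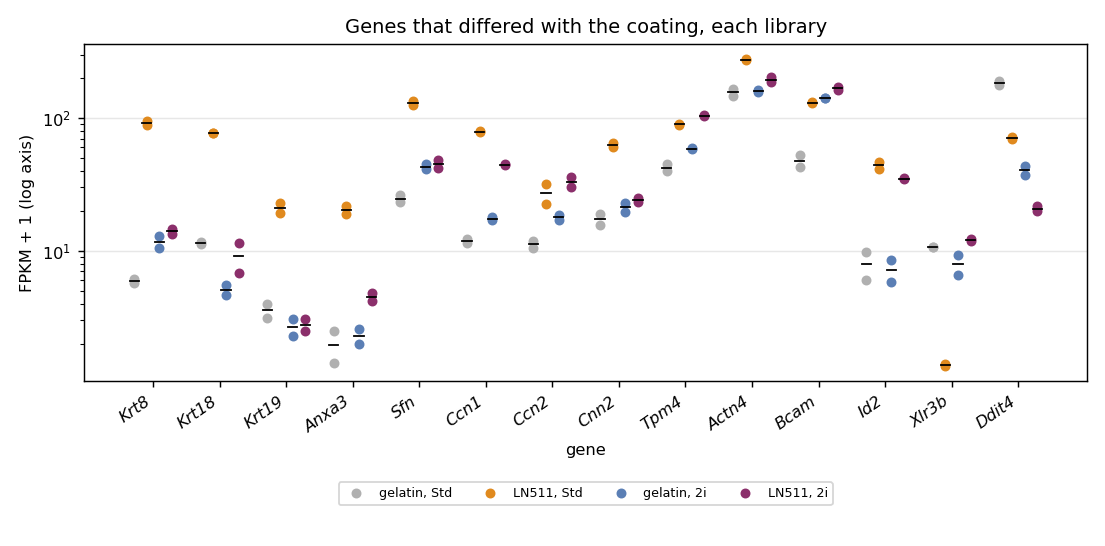
FPKM + 1 on a log axis for 14 genes in each of the 8 libraries, coloured by coating and medium, with a black line at the mean of the 2 libraries of a group. Krt8 lies at 90.4 FPKM in the LN511 Std group and between 4.98 and 13.0 FPKM in the other groups, while Id2 is higher on LN511 in both media.

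In 2i medium, 2 genes passed between coatings, both higher on LN511. With a library of LN511 in 2i left out, most called genes were lower. Ccn1 rose from 16.5 ± 0.52 to 43.5 ± 0.72 FPKM (log2 1.35, SE 0.11, limma adjusted p = 0.0369). Prdx6, a peroxiredoxin gene (mm10 chromosome 1, 161240112 to 161251210), rose from 56.0 ± 4.22 to 141 ± 18.1 FPKM (log2 1.31, SE 0.11, limma adjusted p = 0.0369). Other large differences missed the threshold: Ddit4 was at 39.3 ± 4.35 FPKM on gelatin and 19.7 ± 1.30 FPKM on LN511, Pdk1 at 10.8 ± 1.73 and 3.41 ± 0.63 FPKM, and Tpm4 at 57.9 ± 0.12 and 103 ± 0.59 FPKM, each with a limma adjusted p of 0.0542. The keratin gene Krt8 was at 10.7 ± 1.67 and 13.0 ± 0.78 FPKM.

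Of the 23 lists, 6 passed in 2i between coatings, each with few or no called members, and none passed with an estimated correlation. The 10 tested 2-cell-like genes had a median log2 fold change of 0.91 with 0 members called (0 adjusted over the list alone; camera adjusted p = 0.000846, adjusted p = 0.246 with an estimated correlation). Zscan4c was at 1.96 ± 0.11 FPKM on gelatin and 5 ± 1.84 FPKM on LN511. The focal adhesion and actin list was higher, with 0 of 27 called (3 adjusted over the list alone; camera adjusted p = 0.0349, adjusted p = 0.246 with an estimated correlation), as was the YAP and SRF list, with Ccn1 called (2 adjusted over the list alone; camera adjusted p = 0.0349, adjusted p = 0.246 with an estimated correlation). Ribosomal protein genes were higher as a list by a median log2 of 0.07 (0 of 26 called, 0 adjusted over the list alone; camera adjusted p = 0.0402, adjusted p = 0.721 with an estimated correlation). Glycolysis genes were lower as a list (0 of 20 called, 4 adjusted over the list alone; camera adjusted p = 0.00766, adjusted p = 0.246 with an estimated correlation), and lipid synthesis genes too (0 of 23 called, 0 adjusted over the list alone; camera adjusted p = 0.0145, adjusted p = 0.246 with an estimated correlation). At an unadjusted p under 0.05, 1228 genes differed. Neither Ccn1 nor Prdx6 passed without gelatin Std replicate 1 (limma adjusted p = 0.112 for both), gelatin Std replicate 2 (0.109), LN511 Std replicate 1 (0.163), LN511 Std replicate 2 (0.163), gelatin 2i replicate 1 (0.0936) or gelatin 2i replicate 2 (0.14), and Ccn1 did not without LN511 2i replicate 1 (0.0595) or LN511 2i replicate 2 (0.0633). Both also missed the threshold with a pseudocount of 0.1 (0.0532) and with only the 4 2i libraries (0.284). Leaving out any 1 Std library left 0 genes. The count was 2 without gelatin 2i replicate 1 and 1 without gelatin 2i replicate 2, other genes than these, 12 without LN511 2i replicate 1 (2 higher and 10 lower on LN511) and 7 without LN511 2i replicate 2 (1 higher and 6 lower). Among lists, leaving out 1 library ended the camera calls (adjusted p in brackets) of focal adhesion and actin genes without LN511 Std replicate 1 (0.0596), LN511 Std replicate 2 (0.0593), gelatin 2i replicate 1 (0.0649), gelatin 2i replicate 2 (0.108) or LN511 2i replicate 1 (0.144), YAP and SRF targets without gelatin 2i replicate 1 (0.0649), gelatin 2i replicate 2 (0.104), LN511 2i replicate 1 (0.121) or LN511 2i replicate 2 (0.0599), lipid synthesis genes without gelatin 2i replicate 1 (0.0794) or LN511 2i replicate 1 (0.0919), glycolysis genes without LN511 2i replicate 1 (0.0919), and ribosomal protein genes without gelatin Std replicate 1 (0.0772), gelatin Std replicate 2 (0.0766), LN511 Std replicate 1 (0.117), LN511 Std replicate 2 (0.116), gelatin 2i replicate 1 (0.365), gelatin 2i replicate 2 (0.0761) or LN511 2i replicate 2 (0.93).

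Averaged over both media, LN511 raised 88 genes and lowered 33 against gelatin, 121 in all. Id2, an inhibitor of bHLH factors, rose from 6.90 ± 2.60 to 43.1 ± 4.06 FPKM in Std and from 6.18 ± 1.89 to 34.0 ± 0.57 FPKM in 2i (mean log2 2.42, SE 0.20, limma adjusted p = 0.00629). Ddah1 rose from 5.84 ± 0.43 to 26.9 ± 0.25 FPKM in Std and from 12.7 ± 0.56 to 29.8 ± 2.55 FPKM in 2i. Trh, the gene of thyrotropin-releasing hormone, fell from 116 ± 0.23 to 42.0 ± 5.96 FPKM in Std and from 76.0 ± 9.75 to 16.0 ± 5.68 FPKM in 2i. Bhlhe40, the long noncoding RNA Neat1, the cytokine signalling inhibitor Socs3 and Vat1 also fell. Of 10 called genes that the naming rule takes for this mean, Ddah1, Krt8 and Ccn1 passed with any 1 library left out, and the other 7 missed the threshold with some library left out (limma adjusted p in brackets). Anxa3, higher on LN511, missed it without LN511 Std replicate 1 (0.0796), LN511 Std replicate 2 (0.0724), gelatin 2i replicate 1 (0.0572) or gelatin 2i replicate 2 (0.0633). Id2 missed it without LN511 Std replicate 1 (0.0555). Neat1 missed it without LN511 Std replicate 1 (0.0555). Trh missed it without gelatin Std replicate 1 (0.0523), gelatin Std replicate 2 (0.0551), LN511 Std replicate 1 (0.0555), LN511 Std replicate 2 (0.0562) or gelatin 2i replicate 1 (0.0549). Bhlhe40 missed it without gelatin Std replicate 1 (0.0628), gelatin Std replicate 2 (0.0645), LN511 Std replicate 1 (0.0555), gelatin 2i replicate 1 (0.0594) or gelatin 2i replicate 2 (0.061). Socs3 missed it without gelatin Std replicate 1 (0.0793), gelatin Std replicate 2 (0.0964), LN511 Std replicate 1 (0.105), LN511 Std replicate 2 (0.0895), gelatin 2i replicate 1 (0.101) or gelatin 2i replicate 2 (0.0729). Vat1 missed it without gelatin Std replicate 1 (0.066), gelatin Std replicate 2 (0.0841), LN511 Std replicate 1 (0.0555), LN511 Std replicate 2 (0.0724), gelatin 2i replicate 1 (0.057), gelatin 2i replicate 2 (0.0729) or LN511 2i replicate 2 (0.0656). With quantile normalization the share of higher genes was 62.2%, against 72.7%.

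Lists that passed for the mean of both media were focal adhesion and actin (5 of 27 higher, 16 adjusted over the list alone; camera adjusted p = 4.98e-11, adjusted p = 0.0321 with an estimated correlation), YAP and SRF targets, trophoblast markers, integrins and laminin receptors and ERK targets, all higher, and lipid synthesis and glycolysis, both lower. Apart from the first, their adjusted p-values with an estimated correlation were 0.132, 0.167, 0.187, 0.187, 0.125 and 0.187, in that order. In 2i alone, trophoblast markers (median log2 -0.02, camera adjusted p = 0.978), integrins and laminin receptors (0.09, 0.703) and ERK targets (0.22, 0.488) did not pass. In Std alone, glycolysis genes did not (camera adjusted p = 0.0563). With a pseudocount of 0.1 the ERK list missed the threshold (camera adjusted p = 0.0574). Leaving out 1 library lost the camera call (adjusted p in brackets) for ERK targets without LN511 Std replicate 2 (0.146), LN511 2i replicate 1 (0.0858) or LN511 2i replicate 2 (0.0627), and integrins and laminin receptors without LN511 2i replicate 1 (0.0622) or LN511 2i replicate 2 (0.0848). The count of 121 fell to 24 without gelatin Std replicate 1, 26 without gelatin Std replicate 2, 8 without LN511 Std replicate 1, 24 without LN511 Std replicate 2 (13 higher and 11 lower), 23 without gelatin 2i replicate 1, 27 without gelatin 2i replicate 2 and 74 without LN511 2i replicate 2.

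The interaction asked whether the coating difference was another in 2i than in Std. It passed for 19 genes, 5 with a higher and 14 with a lower coating change in 2i. Among the latter with a mean of 5 FPKM or more in some group, Krt8 differed most (Rbm12b1 and Ddias, under 5 FPKM and listed at 0 in whole groups, differed more): LN511 raised it by a log2 fold change of 3.93 in Std and its change in 2i was lower by 3.66 (interaction log2 -3.66, SE 0.23, limma adjusted p = 0.0114). Sfn, the gene of the epithelial 14-3-3 sigma protein, was at 23.7 ± 2.21 FPKM on gelatin and 128 ± 5.77 FPKM on LN511 in Std, and at 42.0 ± 2.50 and 44.2 ± 4.25 FPKM in 2i. Lgals1, the galectin-1 gene, was at 29.8 ± 5.62 and 133 ± 11.1 FPKM in Std, and at 31.9 ± 0.76 and 33.2 ± 2.44 FPKM in 2i. Anxa1 and Cyb5r1 had the same sign of interaction. In the other direction, Xlr3b, Xlr3a, Hnrnph3, Atp5a1 and Mrgpra6 were lower on LN511 in Std, and the ATP synthase gene Atp5a1 was at 575 ± 13.8 and 247 ± 18.6 FPKM there and at 510 ± 9.81 and 532 ± 27.1 FPKM in 2i. None of these 10 genes, Krt8 to Mrgpra6, passed without gelatin Std replicate 1 (limma adjusted p = 0.065 to 0.129), gelatin Std replicate 2 (0.077 to 0.134), LN511 Std replicate 1 (0.116 to 0.195) or LN511 Std replicate 2 (0.0597 to 0.17). Krt8 alone of them passed without gelatin 2i replicate 1 (the others at 0.0627 to 0.134) or gelatin 2i replicate 2 (0.0832 to 0.137), and Krt8, Sfn and Atp5a1 without LN511 2i replicate 1 (the others at 0.0742 to 0.0955) or LN511 2i replicate 2 (0.0518 to 0.0807). Hnrnph3, Anxa1 and Cyb5r1 missed the threshold with a pseudocount of 0.1 (0.0515), Anxa1 and Cyb5r1 with no filter (0.0524 to 0.0526) and Mrgpra6 with quantile normalization (0.0562).

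The focal adhesion and actin list had the lowest interaction p of the 23 lists, with a median of -0.67 and 1 of 27 genes called (11 adjusted over the list alone; camera adjusted p = 7.7e-07, adjusted p = 0.0791 with an estimated correlation). Trophoblast markers followed, with Krt8 called of 15 (8 lower adjusted over the list alone; camera adjusted p = 1.14e-05, adjusted p = 0.113 with an estimated correlation). The others with a camera adjusted p under 0.05 were 2-cell-like genes (0.000315), ribosomal protein genes (0.000315), integrins and laminin receptors (0.0233), Nodal signalling genes (0.0261) and mesendoderm markers (0.0261), none with an estimated correlation (adjusted p = 0.113, 0.384, 0.231, 0.34 and 0.34 with an estimated correlation). Lists that passed in 1 comparison and not in its counterpart, but not for the interaction, were Wnt and beta-catenin targets (camera adjusted p = 0.242), core and shared pluripotency (0.726), germline genes (0.242), glycolysis (0.552), ERK targets (0.242) and neuroectoderm markers (0.242). A pseudocount of 0.1 ended the camera calls of mesendoderm markers (adjusted p = 0.081) and Nodal signalling genes (adjusted p = 0.0555). Camera interaction calls lost on leaving out 1 library, with the adjusted p in brackets, were those of Nodal signalling genes without gelatin Std replicate 2 (0.119), LN511 Std replicate 1 (0.0831), gelatin 2i replicate 2 (0.0982) or LN511 2i replicate 2 (0.0961), mesendoderm markers without gelatin Std replicate 2 (0.0826), LN511 Std replicate 2 (0.0982), gelatin 2i replicate 1 (0.1) or LN511 2i replicate 1 (0.119), and integrins and laminin receptors without LN511 2i replicate 1 (0.119). Leaving out a library left 0 interaction genes without gelatin Std replicate 1, gelatin Std replicate 2 or LN511 Std replicate 1, 2 without LN511 Std replicate 2 (both with a higher coating change in 2i), gelatin 2i replicate 1 or gelatin 2i replicate 2 (1 in each direction for each), 6 without LN511 2i replicate 1 and 11 without LN511 2i replicate 2. At an unadjusted p under 0.05, 1251 genes passed.

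**Figure D3:**
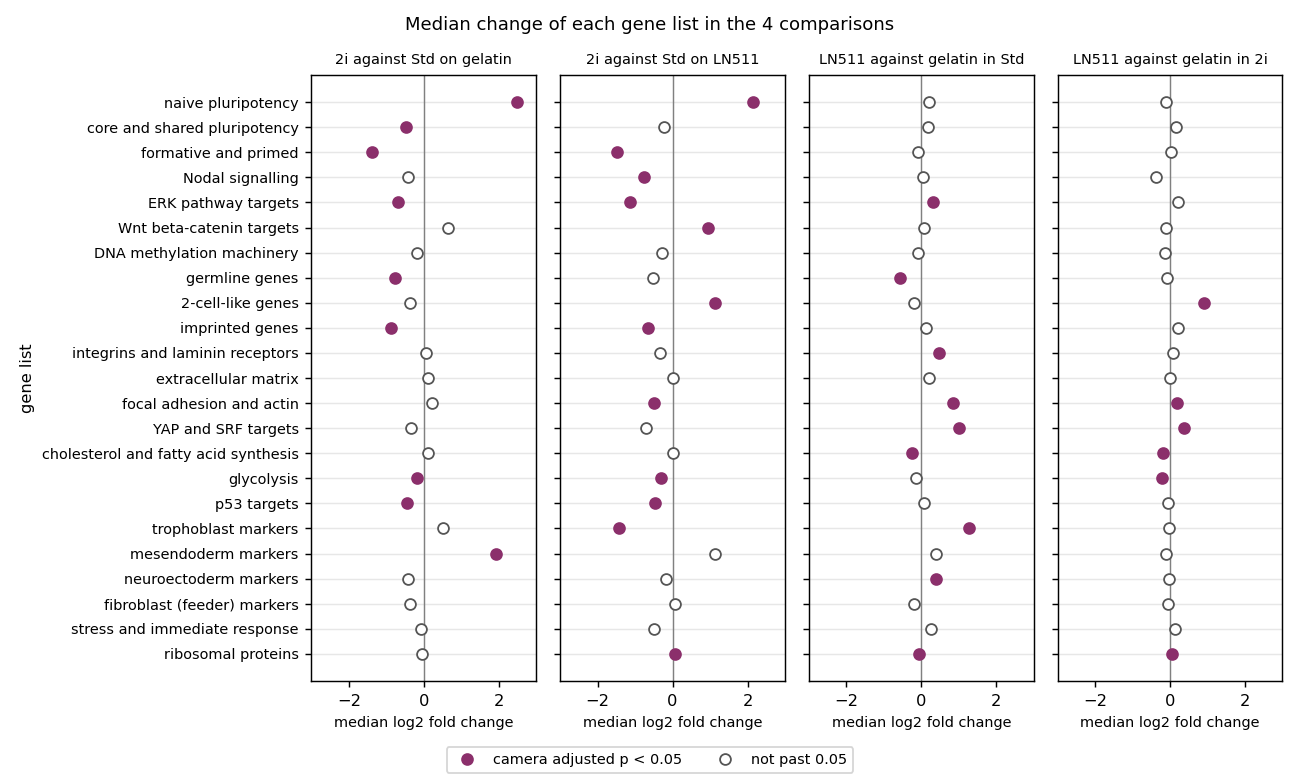
Median log2 fold change of the tested members of 23 gene lists in the 4 comparisons of 2 groups, filled where the camera test with the preset correlation had an adjusted p under 0.05. Naive pluripotency lies at 2.49 on gelatin and 2.15 on LN511 in the medium comparisons, and focal adhesion and actin at 0.85 in Std and 0.19 in 2i in the coating comparisons.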

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

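The tests for fibroblasts, for trophoblast-like cells, for equal effect sizes and for splits of the libraries were chosen after the results they bear on had been seen. Tests of chromosome gain and of assembled transcripts were set before their results were seen.

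The coating difference depended on the medium, by the interaction test, for 19 genes. Among the named ones the interaction log2 fold change was 3.57 for Xlr3b, 2.81 for Xlr3a, 1.65 for Hnrnph3, 1.28 for Atp5a1, 0.98 for Mrgpra6, -3.66 for Krt8, -3.31 for Anxa1, -2.32 for Sfn, -2.32 for Cyb5r1 and -2.08 for Lgals1. By list, the median interaction log2 fold change was -0.67 for focal adhesion and actin, -1.36 for trophoblast markers, -0.38 for integrins and laminin receptors, -0.89 for mesendoderm markers, -0.82 for Nodal signalling, 0.98 for 2-cell-like genes and 0.12 for ribosomal proteins. These 7 lists passed with the preset correlation, and none did with an estimated one (adjusted p = 0.0791 to 0.384 with an estimated correlation).

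Krt8, Krt18, Krt19, 9 of 27 focal adhesion and actin genes and 2 of 11 YAP and SRF targets (as a list, adjusted p = 0.103 with an estimated correlation) were higher on LN511 in Std. Fibroblasts among the cells are argued against, since Col1a1, Col1a2 and Col3a1 reached at most 0.764 FPKM in the LN511 Std libraries. A chromosome gain in all cells is argued against too, since the chromosome median farthest from that of all genes was 0.113 (log2, chromosome 6) and chromosome 15, which holds Krt8 and Krt18, was at 0.017. Reads lost to assembled transcripts stay open as a cause. A test that covered 138 of the 216 called genes found no excess of calls among genes with a 0 in the gene table. Among genes with a 0 in the gene table the share called was 0.66 of that among genes without one. The odds ratio was 0.65 (confidence interval 0.45 to 0.97), and the ratio of shares was under the limit set beforehand. Of the 138 called genes, 96 have such a 0 in a Std library, and whether the reads lost differ between coatings was not tested. The other called genes were not covered, since 60 have no row in the gene table and 18 fall in neither kind. Trophoblast-like cells in these cultures stay open, as does a change of the stem cells with the coating: 11 trophoblast markers other than keratins had a median log2 fold change of 1.00 (camera p = 0.0034, p = 0.0424 with an estimated correlation), of which Hand1 alone passed, but these markers belong to a list already seen to be higher, and Cdx2 and Eomes were at 0.28 and 0.17.

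Far fewer genes passed between coatings in 2i (2) than in Std (216). For the genes most changed in Std, coating effects of equal size that missed the threshold in 2i are argued against. For the 216 genes most changed between the libraries numbered 1 in Std, the mean change in the same direction was 0.61 (log2) between the libraries numbered 2 in Std and 0.105 in 2i, a ratio of 0.17 (bootstrap interval over genes -0.01 to 0.38). When genes were chosen on the libraries numbered 2, the ratio was 0.01. The interval does not cover the spread between cultures. No genes were chosen on the 2i libraries, so coating effects of that size on other genes in 2i were not tested. The interaction test called 19 genes, but these calls were lost with some single libraries left out. Beyond these genes, a coating effect that depends on the medium stays open as a hypothesis.

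For the mean coating contrast, a fit with medium as a term called 32 genes for the real split of the 8 libraries. Of the 18 splits with 2 libraries of each medium on each side, 1 gave as many, the real one, and the highest of the others gave 3. These splits are too few for a share under 0.05. One signal lies outside the main measurement. Of the assembled transcript numbers, 12143 were above 0 in 1 library only, and 0 in all 8, so they could not be compared between libraries.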

How the results depend on the processing

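Keeping genes with a doubtful 0 and testing only genes above 0 in all 8 libraries were alternatives chosen after seeing the data. Median-of-ratios and quantile scaling, robust eBayes and a pseudocount of 0.5 left every count of called genes within 1.5 times of the reported one. Below, counts are in the order 2i on LN511, 2i on gelatin, LN511 in Std, LN511 in 2i, mean coating, interaction, against 1905, 1583, 216, 2, 121 and 19. With the deposited gene table they were 336, 273, 263, 187, 316 and 307, the one alternative that turned the direction of named genes. Its zeros entered that fit as values, and whether they alone caused the turns was not tested. A log2 fold change of at least 1 left 1153, 974, 134, 2, 41 and 18. With only the libraries of the contrast, the first 4 were 962, 998, 6 and 0, with fewer samples behind the spread. For LN511 in 2i, where 2 genes make the count unsteady, a pseudocount of 0.1 gave 0, no filter 15, a filter of 5 FPKM 17, doubtful zeros kept 42 and genes above 0 in all 8 libraries 14; the cause was not tested. The interaction gave 31 with no filter, 53 with doubtful zeros kept and 37 for genes above 0 in all 8 libraries, and the last gave 192 for the mean coating; the cause was not tested. Leaving out 1 library gave ranges of 861 to 1625, 648 to 1516, 9 to 199, 0 to 12, 8 to 120 and 0 to 11, where the group left with 1 library is assumed to vary like the others.

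Lists passing (12, 9, 9, 6, 7 and 7 in the order above) numbered 1, 1, 1, 0, 1 and 0 with an estimated correlation and 21, 18, 15, 5, 12 and 10 by fry, which does not compare a list with other genes. Leaving out 1 library gave 9 to 13, 8 to 9, 7 to 10, 2 to 5, 5 to 10 and 5 to 8. With a pseudocount of 0.1 the lists numbered 10, 9, 9, 6, 7 and 5, and with the replicate number as a block 12, 9, 9, 6, 6 and 7. The ERK list in the mean coating contrast was lost in both (adjusted p = 0.0574 and 0.0579). With the replicate number as a block, counts of genes were 1497, 1219, 80, 0, 39 and 1; the correlations of deviations between same-numbered libraries were -0.02 to 0.019, so the numbers do not pair the samples. No list that passed turned direction under the block, median-of-ratios scaling or leaving out a library.

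With the gene table the following called genes turned. Log2 fold changes for 2i against Std on gelatin became Calcoco2 -2.51, Pim2 3.07, Hes6 1.13, Cldn6 0.89, Dnmt3a 1.25, Mest 0.65, Bcam -2.86, Nid1 -1.71, Sparc -2.77, Vim -2.71, Ilk -1.92, Pgk1 4.34, Bnip3 1.27, Pdk1 3.55, Rplp0 5.33, Klf4 -4.40. Log2 fold changes for 2i against Std on LN511 became Calcoco2 -3.75, Tcf15 2.13, Utf1 6.37, Dnmt3a 2.58, Spry4 1.34, Epha2 5.11, Ddx4 1.02, Sdc2 -0.027, Itgb5 -4.29, Nid1 -3.55, F3 0.48, Idi1 2.48, Nes 0.30, Txnip 0.90, Rplp0 10.98, Klf4 -2.35. Log2 fold changes for LN511 against gelatin in Std became Zic2 0.72, Epha2 -2.97, Col4a1 -0.85, Cnn2 -1.15. Log2 fold changes for LN511 against gelatin in 2i became Prdx6 -2.95. Log2 fold changes for the mean of both media became Trh 0.28, Bhlhe40 0.45, Vat1 1.84. Among other checks of named called genes outside leave-one-out, 2456 kept direction and call and 263 lost the call without turning. The latter include Syce1 and T on gelatin, at a log2 fold change of 0 with the gene table. With a library left out, 1354 kept both and 438 lost the call without turning. Depth limits genes near 1 FPKM, where by the estimated depth a value rests on few fragments.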

Other observations

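Apart from the lists, 22 genes moved in opposite directions with the medium on the 2 coatings, and several that were well expressed show a common shape, named here after their values were seen. Sfn, Lasp1, Tagln2, Plin2 and Fhl1 rose in 2i on gelatin and fell in 2i on LN511, and all but Tagln2 (limma adjusted p = 0.0675) also passed as higher on LN511 in Std. Plin2, which encodes a coat protein of lipid droplets, was at 6.21 and 8.73 FPKM in the gelatin Std libraries, 37.1 and 43.1 in LN511 Std, 17.9 and 33.3 in gelatin 2i, and 16.6 and 13.2 in LN511 2i. Zic2 did the reverse, at 26.0 and 26.3, 8.95 and 6.42, 14.9 and 11.1, and 13.2 and 15.2 FPKM. The set was chosen for opposite changes with the medium, which is what the interaction measures, so the interaction test lends it no support. The same choice favours a coating difference in Std in the same libraries, so that difference lends it no independent support either. For the genes of this shape the interaction had limma adjusted p = 0.0114 for Sfn, 0.054 for Fhl1, 0.0727 for Plin2, 0.0833 for Lasp1, 0.0975 for Tagln2 and 0.1 for Zic2.

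Ddit4, Bnip3 and Pdk1, which hypoxia-inducible factor (HIF) is known to induce, were lower on LN511 in the mean coating contrast (log2 -1.17, -0.76 and -0.81, limma adjusted p = 0.00333, 0.0154 and 0.0385). In Std, Ddit4 and Bnip3 passed (0.0051 and 0.0325) and Pdk1 did not (0.631), and in 2i none did (0.0542, 0.106 and 0.0542). Slc2a1, a glycolysis list member like Bnip3 and Pdk1, passed as higher on LN511 in Std (log2 0.57, limma adjusted p = 0.0365). With the replicate number as a block Slc2a1 missed the threshold (limma adjusted p = 0.0795). In Std, Bnip3 missed the threshold without gelatin Std replicate 1 (0.088) or 2 (0.14), LN511 Std replicate 1 (0.148) or 2 (0.109), or gelatin 2i replicate 1 (0.07) or 2 (0.0705). Ddit4 missed it there without LN511 Std replicate 1 (0.0703) or 2 (0.0513), and both did with only the 4 Std libraries (Bnip3 0.0936, Ddit4 0.0557). Scaling between libraries is argued against by a test chosen after seeing the result: after median-of-ratios scaling their median in the mean coating contrast was -0.838 (log2). The hypothesis of lower HIF activity on LN511 was tested on other HIF targets, in a list written before their result as a set was seen. In the mean coating contrast, 0 of 19 tested passed singly, 7 were above 0 and the median was -0.237 (camera p = 0.00491, p = 0.0378 with an estimated correlation). In Std alone 9 of 19 were above 0 and the median was -0.039 (camera p = 0.0819, p = 0.132 with an estimated correlation). In 2i alone 6 were above 0 and the median was -0.197 (camera p = 0.0165, p = 0.0598 with an estimated correlation). Of these genes 3 belong to the fixed lists, and without them camera p in the mean coating contrast was 0.0112 (p = 0.0529 with an estimated correlation). The hypothesis remains undecided: the result in Std missed the threshold set for it.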
